A study of Mus musculus with 24 samples.

How the data were processed

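Liver RNA of 24 male BALB/c mice was measured on Affymetrix 3' expression arrays, with 1 array per mouse. The 4 groups of 6 mice were taken from the sample labels: untreated mice on a purified AIN93G diet (control), mice injected with 185 mg/kg streptozotocin on that diet (STZ), and mice injected with streptozotocin and given the diet with 0.1% or 0.5% quercetin for 14 days. The labels state that the STZ mice were picked by their non-fasting glucose before the diets began and that cages held 3 mice, but they do not tie a mouse to a cage. All tests therefore treat the 6 mice of a group as independent. An effect of the cage could not be separated from that of the group. The array numbers shared by the groups come without any statement that they mark a cage, a day or a batch.

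Biotin-labelled cRNA was made from total RNA, per the labels' protocols. The deposited values were linear probe set intensities, 1 per probe set and array, for 45101 probe sets including 64 control probe sets. The summary algorithm and any scaling before deposition are stated neither in the labels nor in the table, and no value is a detection call. The values were all above 0 and right-skewed, so the scale was read as linear, no centring was present, and a higher value meant more signal. The target of any scaling stays unknown, and no scaling between arrays was visible. Mean intensity ranged from 61.0 to 102.0 per array, a ratio of 1.67, and the ratio of the highest to the lowest 75th percentile was 1.76. The median intensities of control replicates 1 to 6 were 7.95, 5.02, 5.48, 4.96, 6.63 and 6.21. Those of STZ replicates 1 to 6 were 6.85, 5.46, 7.53, 5.87, 6.42 and 7.98. Those of the 0.1% quercetin replicates were 6.27, 5.93, 7.84, 5.62, 6.05 and 7.09, and those of the 0.5% quercetin replicates 6.06, 7.34, 7.17, 6.21, 6.23 and 6.33. The number of arrays limited the precision of each value.

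The deposited intensities were quantile normalized across the 24 arrays and then converted to log2(value + 16). The plan fixed before the data were examined had named no normalization, on the assumption of scaled values, with quantile normalization as an alternative. The change was made when the array averages were seen to differ and before any test was run, and the calls on the values as deposited are given beside the counts of genes. The constant of 16 understates folds of genes near the floor. Probe sets were named from the platform table. Of these, 34958 had 1 gene symbol, 932 had several and 9211 had none listed, and 34754 of those with 1 symbol matched a gene ID in the GRCm38.p6 gene table, which changed 0 symbols. That table was used for names only, and no coordinates are given because no build is stated for the arrays. Each gene was represented by its probe set with the highest mean over all arrays, chosen among probe sets with 1 symbol. Genes whose representative lay under the 40th percentile of all probe set means were left out, so that 13117 of 18193 genes were tested. A symbol of a gene list was matched through an older name only where it was no current symbol of another gene.

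Groups were compared with limma 3.58.1 in R 4.3.3, in 1 fit with 4 group means over all arrays, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The dose trend was fitted to the 18 STZ-treated mice with the percentage of quercetin in the diet as a numeric term, so its slopes are log2 changes per 1% of the diet. The design, the alternatives, the rule for named genes and 38 gene lists, covering liver metabolism, stress and immune pathways and markers of other cell types, were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01 and adjusted over the 38 lists of a comparison. Some lists share members, so their shifts are not independent. Camera with an estimated correlation and fry were alternatives. An exact permutation test of the mean of each list per mouse (924 arrangements of 6 against 6 mice, two-sided) was added after the data were seen. The named genes were the 5 largest rises and the 5 largest falls past the threshold, the 3 largest called changes of each of the 8 lists with the smallest camera p, and 15 genes fixed in advance, of which 13 were tested. Where no gene passed, the 3 genes with the smallest p were named and said not to pass, and where up to 20 passed, all were named. Any other gene is said to have been chosen after its values were seen.

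The reversal of STZ changes was measured as a score per mouse, the mean over genes called on replicates 1 to 3 of control and STZ, signed by their change. Scores of quercetin mice were compared with those of STZ replicates 4 to 6 by an exact permutation test (84 arrangements, two-sided). A position of each mouse between the control mean and the STZ mean was computed from genes called, and means taken, without the mouse being placed. The quality of each array was described by the 3' minus 5' log2 difference of the Gapdh and beta-actin control probe sets. Comparisons that share control or STZ arrays were set beside simulated unchanged groups, 100 draws for overlaps and 1000 for correlations. The procedure was tested on simulated data with 13117 genes and 6 arrays per group in the STZ against control comparison. It recovered 36 of 50 genes changed by 0.5 on the log2 scale and 50 of 50 at each of 1, 2 and 3, with 10 calls among unchanged genes. It made 0 calls in a comparison of the doses with no simulated change.

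The alternatives were no filter, a filter at the 60th percentile, the mean of all probe sets of a gene, all probe sets, median scaling, added constants of 1 and 64, a moderated variance with trend and robust estimation, array weights, a fit on the compared groups alone, the replicate number as a block, and leaving out each mouse in turn. Added after the data were seen were the values as deposited, scaling to a trimmed mean, the fit without 0.5% quercetin replicates 5 and 6, and the Gapdh, beta-actin and clock score covariates.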

Results

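Hepatic gene expression was measured in 24 male BALB/c mice in 4 groups of 6, with 1 array per mouse. Streptozotocin is an alkylating glucose analogue that destroys insulin-producing beta cells, and quercetin is a plant flavonol. The groups were untreated mice (control), STZ mice on the purified diet, and STZ mice on that diet with 0.1% or 0.5% quercetin. Correlations between arrays lay between 0.964 and 0.989. The first principal component carried 22.4% of the variance and had a mean of -15.4 ± 1.81 (SD, n = 6) in controls, 7.04 ± 5.73 in STZ mice, 10.3 ± 7.71 at 0.1% and -1.99 ± 12.8 at 0.5% quercetin. At 0.5%, replicates 5 and 6 lay at -17.2 and -19.2 on it, beside the controls.

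The first comparison, STZ against control on the same diet, gave the hepatic changes that went with streptozotocin treatment. In livers of STZ mice, the lists of p53 targets, interferon response genes, NRF2 targets, MHC class II genes and CAR and PXR genes shifted upward, with 13 of 24, 9 of 23, 6 of 27, 5 of 7 and 5 of 19 members higher. The list of male-biased genes shifted downward, with 7 of 18 lower. Of the 17 lists past camera in this comparison, 1 (MHC class II) passed with an estimated correlation. With fry, 14 of 38 lists passed, and 14 passed the exact permutation test of the list mean per mouse. Cdkn1a, a cell cycle inhibitor induced by p53, rose 8.78-fold from a log2 level of 5.52 ± 0.52 to 8.66 ± 0.20 (SD, n = 6 each), a log2 change of 3.13 (SE 0.50, limma adjusted p = 0.00063). Every STZ mouse lay above every control mouse for Cdkn1a. The largest rise was that of the representative probe set of Cplane1, a gene of cilium formation, with a log2 change of 4.68 (SE 0.62, adjusted p = 9.17e-05). For Cplane1, 3 other probe sets over the filter also had higher means, by 1.81, 2.57 and 1.31, and the other 2 differed by -0.15 and -0.06. In all, 266 genes were higher and 222 lower in STZ mice (limma, 13117 genes tested), 49 and 17 of them by at least 2-fold, and 2194 had an unadjusted p under 0.05.

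Of 24 p53 target and DNA damage genes tested, 13 rose, 1 fell and 10 did not pass the test. The counts adjusted over the list alone were 15 higher and 2 lower. Phlda3, a repressor of Akt signalling, rose by 2.52 (SE 0.31, adjusted p = 3.74e-05) and Trp53inp1, a stress-induced p53 cofactor, by 1.53 (SE 0.23, adjusted p = 0.000351), each above all controls in 6 of 6 mice. The list shifted upward with a mean log2 change of 0.71 (camera adjusted p = 1.41e-12). Its adjusted p = 0.0723 with an estimated correlation did not pass. Of 23 interferon response genes, 9 rose and none fell (16 and 0 adjusted over the list alone), among them Usp18, which restrains interferon signalling, by 1.15 (SE 0.25), Gbp3, a guanylate-binding GTPase, by 1.04 (SE 0.18), and Irf7, a transcription factor, by 0.97 (SE 0.26). The list had a mean change of 0.48 (camera adjusted p = 2.18e-15, and adjusted p = 0.0723 with an estimated correlation). Of 7 MHC class II genes, which present antigen to T cells, 5 rose and none fell (6 and 0 adjusted over the list alone). H2-Aa rose by 1.18 (SE 0.21), H2-Eb1 by 1.17 (SE 0.17) and the invariant chain gene Cd74 by 0.92 (SE 0.19), each in 6 of 6 mice above all controls. The MHC class II list had a mean change of 0.73 (camera adjusted p = 3.36e-10) and alone among the 17 lists past the threshold also passed with an estimated correlation (adjusted p = 0.0262). Of 14 macrophage and Kupffer cell markers, 4 rose and none fell (11 and 0 adjusted over the list alone), among them Mpeg1 by 0.70 (SE 0.16), C1qb by 0.62 (SE 0.15) and Cd5l by 0.58 (SE 0.14), with a list mean of 0.32 (camera adjusted p = 2.27e-08, and adjusted p = 0.0892 with an estimated correlation).

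Drug-metabolizing genes under the nuclear receptors CAR and PXR shifted upward. Of 19 tested, 5 rose and none fell (11 and 0 adjusted over the list alone), with a mean of 0.71 (camera adjusted p = 3.98e-09, and adjusted p = 0.0745 with an estimated correlation). The cytochromes P450 Cyp2c39, Cyp2b9 and Cyp2c38 rose by 2.85 (SE 0.47), 2.59 (SE 0.48) and 2.02 (SE 0.46), each above all controls in 6 of 6 mice. Of 27 targets of NRF2, the regulator of antioxidant and conjugating enzymes, 6 rose and none fell (12 and 0 adjusted over the list alone), with a mean of 0.43 (camera adjusted p = 1.12e-10, and adjusted p = 0.0723 with an estimated correlation). The glutathione transferase Gsta2 rose 4.42-fold, by 2.14 (SE 0.42), the epoxide hydrolase Ephx1 by 1.63 (SE 0.25) and the glutathione transferase Gstm2 by 0.87 (SE 0.15), whereas the NRF2 target Hmox1, heme oxygenase, differed by 0.11 (SE 0.14, adjusted p = 0.755). Nnmt, which methylates nicotinamide, rose by 2.70 (SE 0.53), and 5 of 6 STZ mice lay above all controls.

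Genes with higher expression in male liver, which depend on pulsed growth hormone, shifted downward, and genes with higher expression in female liver shifted upward. Of 18 growth hormone and male-biased genes, 7 fell and none rose (8 lower and 0 higher adjusted over the list alone), with a mean of -0.57 (camera adjusted p = 3.75e-06, and adjusted p = 0.0968 with an estimated correlation). Hsd3b5, a male-specific steroid dehydrogenase, fell by 1.89 on the log2 scale (SE 0.52, adjusted p = 0.0369), below all controls in 6 of 6 mice, and the growth factor receptor gene Egfr fell by 1.42 (SE 0.35), below all controls in 5 of 6. The other Egfr probe sets over the filter differed by -1.40, 0.06, -0.69, -0.18 and -0.50. Igf1, the main growth factor induced by growth hormone, differed by -0.07 (SE 0.09, adjusted p = 0.761). Of 14 female-biased genes, 4 rose and none fell (8 and 0 adjusted over the list alone), with a mean of 0.73 (camera adjusted p = 6.62e-08, and adjusted p = 0.0745 with an estimated correlation). Cyp17a1, a steroid hydroxylase, rose by 1.77 (SE 0.36) and the cytochrome P450 gene Cyp3a44 rose 2.29-fold. The female-biased list shares members with the CAR and PXR list, among them Cyp2b9, so these shifts are not independent.

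Among genes of fuel metabolism, Igfbp1, an insulin-repressed binding protein of insulin-like growth factors, rose by 1.41 (SE 0.33, adjusted p = 0.0138), and Cyp4a14, a PPARalpha-induced fatty acid hydroxylase, rose by 2.27 (SE 0.62, adjusted p = 0.0358). Pck1, which encodes an enzyme of gluconeogenesis, was above all controls in 6 of 6 mice with a difference of 0.58 (SE 0.17) that did not pass (adjusted p = 0.0536), and passed without 0.5% quercetin replicates 5 and 6 in the fit (adjusted p = 0.0394). G6pc, glucose-6-phosphatase, differed by 0.39 (SE 0.30, adjusted p = 0.569). The gluconeogenesis list, with 2 of 13 genes higher (4 adjusted over the list alone), had a mean of 0.30 (camera adjusted p = 3.52e-05, and adjusted p = 0.0745 with an estimated correlation). Of 24 genes of amino acid breakdown and the urea cycle, 4 rose and none fell (7 and 0 adjusted over the list alone), with a mean of 0.26 (camera adjusted p = 9.24e-07, and adjusted p = 0.24 with an estimated correlation), among them the urea cycle gene Asl by 1.27 (SE 0.29), the methionine adenosyltransferase gene Mat1a by 1.01 (SE 0.17) and Oat, which breaks down ornithine, by 0.98 (SE 0.24). PPARalpha targets had a mean of 0.22, with 2 of 26 higher (3 adjusted over the list alone; camera adjusted p = 0.00021, and adjusted p = 0.193 with an estimated correlation). The lipogenic genes Srebf1, Fasn and Scd1 differed by -0.53 (SE 0.19), -0.24 (SE 0.28) and -0.07 (SE 0.18) and did not pass (adjusted p of 0.121, 0.725 and 0.888). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by -0.15 (SE 0.67), the aryl hydrocarbon receptor target Cyp1a1 by 0.01 (SE 0.09) and the metallothionein gene Mt1 by 1.10 (SE 0.46), and none of these passed (adjusted p of 0.942, 0.982 and 0.212).

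The immunoglobulin heavy chain gene Ighm fell by 1.63 (SE 0.30, adjusted p = 0.00283), below all controls in 6 of 6 mice, and the B and plasma cell list had a mean of -0.45, with 2 of 6 genes lower (3 adjusted over the list alone; camera adjusted p = 0.00115, and adjusted p = 0.0745 with an estimated correlation). The largest fall was that of Serpina4-ps1, a serpin pseudogene, by 2.56 (SE 0.50), followed by Serpina12, which encodes the adipokine vaspin, by 2.08 (SE 0.52). The other lists past camera were lipoproteins (mean 0.21, with 6 of 23 higher, and 6 higher and 1 lower adjusted over the list alone), the unfolded protein response (0.14, with 2 of 23 higher and 2 adjusted over the list alone), the cell cycle (0.12, with 2 of 29 higher, and 4 higher and 1 lower adjusted over the list alone), stellate cell and matrix markers (0.11, with 1 of 17 higher, and 3 higher and 1 lower adjusted over the list alone) and exocrine pancreas markers (-0.40, with 1 of 5 lower and 2 adjusted over the list alone). Their adjusted p values with an estimated correlation were 0.0892, 0.461, 0.433, 0.358 and 0.0723. The call of the lipoprotein list ended on the values as deposited (adjusted p = 0.137), under median scaling (adjusted p = 0.69) and under trimmed mean scaling (adjusted p = 0.471). Among the lipoprotein genes that rose, chosen after their values were seen, were the fatty acid transporter gene Cd36 by 2.14 and Apoa4 by 0.77. The other calls on these lists were Hsp90b1 and Pdia6 (unfolded protein response), Ccnd1 by 1.36 and Cdk1 by 0.47 (cell cycle), Dcn by 0.41 (matrix) and Cela1 by -1.38 (exocrine pancreas), also chosen after their values were seen.

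Of the 21 lists that did not pass in this comparison, glycolysis, glycogen metabolism, fatty acid synthesis and cholesterol synthesis had mean changes of 0.02, 0.01, -0.10 and -0.07 between STZ and control. The direction of all called lists and called named genes was the same under each scaling of the arrays. The share of called genes that were higher, 54.5%, was 74.5% on the values as deposited (120 higher and 41 lower) and 37.9% under median scaling (170 higher and 278 lower). The counts fell to 146 higher and 100 lower without STZ replicate 6, and the count of lower genes was 147, 130, 114 and 131 without STZ replicate 2, STZ replicate 3, control replicate 3 and control replicate 4. The Gapdh 3' minus 5' difference of the arrays, a measure of RNA quality, moved with all these gene groups, at -0.04 ± 0.16 in controls and -0.34 ± 0.09 in STZ mice (SD, n = 6 each, exact permutation p = 0.00216, adjusted p = 0.0519 over 24 tests). With that difference in the fit, 4 genes were higher and 1 was lower, namely Ly6d, Ifi27l2b, Aebp2 and Phlda3 against Tcf24, which include genes chosen after their values were seen.

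**Figure D1:**
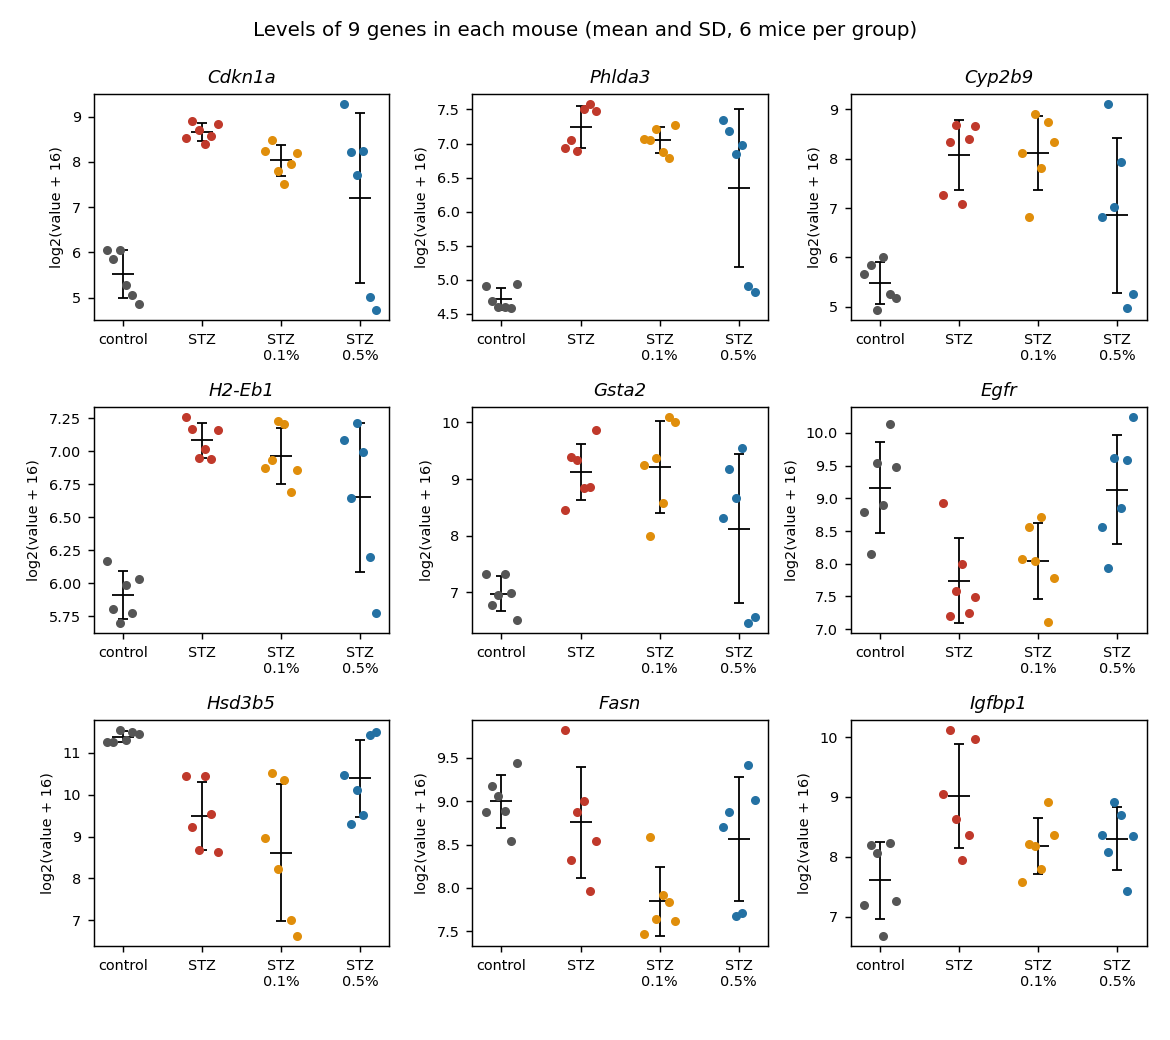
Levels as log2(value + 16) of 9 genes, with a point per mouse and the mean and SD of each group of 6 mice. Cdkn1a, Phlda3, Cyp2b9, H2-Eb1 and Gsta2 were higher in STZ mice than in all controls, and for Cdkn1a, 0.5% quercetin replicates 5 and 6 lay at 5.01 and 4.72, against a control mean of 5.52.

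The comparison of 0.1% quercetin with STZ addressed what the lower dose added to the diabetic liver. The lists of fatty acid synthesis, cholesterol synthesis, glycogen metabolism, and glycolysis and glucose uptake had lower means at 0.1% quercetin, and no gene passed by itself. Genes of fatty acid and triglyceride synthesis shifted downward together, with 19 of 21 below their STZ mean and a mean change of -0.36 (camera adjusted p = 1.73e-09, and adjusted p = 0.0842 with an estimated correlation). Fasn, fatty acid synthase, differed by -0.91 (SE 0.28, adjusted p = 0.871), with 5 of 6 mice below all STZ mice, and Scd1, a fatty acid desaturase, by -0.56 (SE 0.18). Among other members, chosen after their values were seen, Acly differed by -1.01, Elovl6 by -0.94 and Me1 by -0.81. All 20 genes of cholesterol synthesis lay below their STZ mean, with a mean of -0.27 (camera adjusted p = 7.11e-06, and adjusted p = 0.674 with an estimated correlation). Glycogen metabolism had a mean of -0.21 over 12 genes (camera adjusted p = 0.000132) and glycolysis and glucose uptake of -0.20 over 8 genes (camera adjusted p = 0.000267), and both passed with an estimated correlation (adjusted p = 0.0146 for each). The mean of each of these last lists was below all STZ mice in 6 of 6 mice, and both passed the exact permutation test of the list mean per mouse (adjusted p = 0.0411 for each), which fatty acid synthesis (adjusted p = 0.165) and cholesterol synthesis (adjusted p = 0.598) did not pass. Adjusted over the list alone, 7 fatty acid, 0 cholesterol, 4 glycogen and 2 glycolysis genes were lower and 0 were higher.

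By limma, 0 genes were higher and 0 lower at 0.1% quercetin than in STZ mice, with 687 at an unadjusted p under 0.05 where 656 were expected by chance. The smallest p was that of Pdk4, a kinase that restrains glucose oxidation, which differed by -0.64 (SE 0.13, adjusted p = 0.356) and lay below all STZ mice in 6 of 6 mice. Next came 1700094D03Rik at -0.42 (SE 0.10) and Fa2h, a fatty acid hydroxylase, at 0.41 (SE 0.10), neither of which passed (adjusted p = 0.871 for each). G6pc differed by -0.97 (SE 0.30), Igfbp1 by -0.84 (SE 0.33), Cdkn1a by -0.62 (SE 0.50) and Mt1 by 0.91 (SE 0.46), with adjusted p of 0.871, 0.885, 0.993 and 0.936. As many lists passed in 62 of 100 splits of these 12 mice.

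The comparison of 0.5% quercetin with STZ addressed the higher dose. As a group, these 6 mice had lower means of several lists that were higher in STZ mice, among them p53 targets, NRF2 targets and female-biased genes, and higher means of male-biased genes. PPARalpha targets, also higher in STZ mice, were not lower, with means over the controls of 0.24 at 0.5% quercetin and 0.22 in STZ mice. Of 24 p53 targets, 20 lay below their STZ mean, with a mean of -0.30 (camera adjusted p = 4.07e-05, and adjusted p = 0.365 with an estimated correlation). NRF2 targets had a mean of -0.24, female-biased genes of -0.34 and male-biased genes of 0.35, with camera adjusted p of 1.28e-05, 0.00148 and 0.000206. Their adjusted p = 0.365 with an estimated correlation was the same for each. CAR and PXR genes had a mean of -0.27, MHC class II genes of -0.27, macrophage markers of -0.15, interferon response genes of -0.14, amino acid breakdown genes of -0.14, the unfolded protein response of -0.13 and glycogen metabolism of -0.10. Bile duct markers (4 genes) had a mean of -0.23 and exocrine pancreas markers (5 genes) of 0.27. These 13 lists passed camera, 0 passed with an estimated correlation (smallest adjusted p = 0.104) and 0 passed the exact permutation test of the list mean per mouse. Adjusted over the list alone, 7 p53 and 2 NRF2 targets were lower, and 1 male-biased gene and 3 exocrine pancreas markers were higher.

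Of these 13 lists, 11 no longer passed without 0.5% quercetin replicates 5 and 6, an alternative chosen after the data were seen. Cdkn1a had a level of 7.20 ± 1.88 (SD, n = 6) in the group, with 5.01 and 4.72 in replicates 5 and 6 and 7.70 to 9.29 in the other 4 mice, and its difference from STZ was -1.46 (SE 0.50, adjusted p = 0.562). On an axis from the control mean at 0 to the STZ mean at 1, replicates 5 and 6 lay at 0.05 and -0.01, the other 4 mice of the group between 0.79 and 0.95, STZ mice between 0.69 and 1.21, 0.1% quercetin mice between 0.71 and 1.22, and controls between -0.01 and 0.15. The Gapdh 3' minus 5' difference moved with these gene groups too, at -0.05 and 0.003 in replicates 5 and 6 against -0.04 ± 0.16 in controls and -0.34 ± 0.09 in STZ mice (SD, n = 6 each). Without replicates 5 and 6, 5 lists passed, of which male-biased genes (0.18) and glycogen metabolism (-0.15) were among the 13. The means of interferon response genes and macrophage markers turned to 0.06 and 0.03, and neither passed. By limma, 0 genes were higher and 0 lower at 0.5% quercetin than in STZ mice, with 985 at an unadjusted p under 0.05. The smallest p were those of Cep78, a centrosomal protein gene, at -0.48 (SE 0.09, adjusted p = 0.219, below all STZ mice in 6 of 6), Sh3pxd2b at -0.48 (SE 0.11, adjusted p = 0.365) and Aff2 at 0.32 (SE 0.08, adjusted p = 0.365), none of which passed. Of 12 fits that each left out 1 mouse, only that without 0.5% quercetin replicate 3 called a gene, Cep78, which fell by 0.54 (adjusted p = 0.0251).

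**Figure D2:**
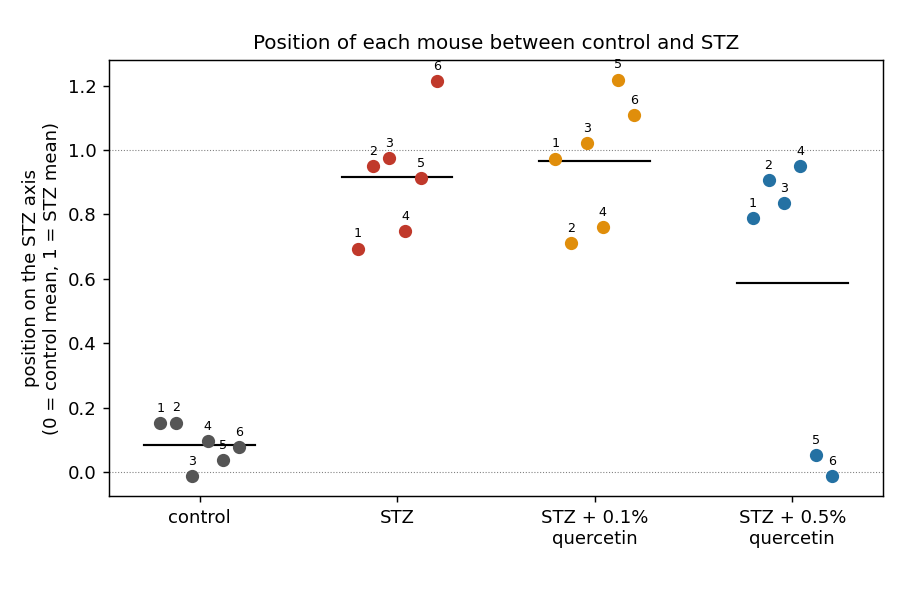
Position of each mouse, numbered by replicate, between the control mean (0) and the STZ mean (1) of genes called without the mouse, with the mean of each group as a line. At 0.5% quercetin, replicates 5 and 6 lay at 0.05 and -0.01 and the other 4 mice between 0.79 and 0.95.

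The doses were compared directly. Genes of fatty acid synthesis had higher means at 0.5% than at 0.1% quercetin, with 19 of 21 higher and a mean of 0.33 (camera adjusted p = 1.12e-06, and adjusted p = 0.231 with an estimated correlation). Cholesterol synthesis genes had a mean of 0.22 and male-biased genes of 0.48, while female-biased genes had a mean of -0.44, NRF2 targets of -0.23, p53 targets of -0.23, acute phase genes of -0.27, CAR and PXR genes of -0.27, amino acid breakdown genes of -0.16, macrophage markers of -0.15 and lipoprotein genes of -0.14. Of these 11 lists past camera, 0 passed with an estimated correlation (smallest adjusted p = 0.231), and 3 kept their direction past the threshold without 0.5% quercetin replicates 5 and 6. In that fit 3 turned direction and did not pass. The p53 targets had a mean of 0.0308 and the macrophage markers of 0.0256. CAR and PXR genes had a mean of -0.0378, while their camera direction turned. Adjusted over the list alone, 5 male-biased genes were higher, 1 NRF2 target was higher and 2 lower, and 1 female-biased and 1 acute phase gene were lower. By limma, 0 genes were higher and 0 lower, with 1094 at an unadjusted p under 0.05. The smallest p were those of Pparg, a regulator of fat storage, at -0.58 (SE 0.10, adjusted p = 0.0874), Nrp1, a semaphorin receptor gene, at 0.88 (SE 0.19, adjusted p = 0.308) and Sdr9c7 at 0.53 (SE 0.12, adjusted p = 0.308), none of which passed. Of 12 fits that each left out 1 mouse, only that without 0.5% quercetin replicate 2 called a gene, Pparg, which fell by 0.67 (adjusted p = 0.00362).

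The trend with the quercetin dose over the 18 STZ-treated mice was fitted per 1% of quercetin. Cep78 had a slope of -0.94 (SE 0.16, adjusted p = 0.0942), Sh3pxd2b of -1.02 (SE 0.19, adjusted p = 0.102) and Abhd17b of 1.05 (SE 0.20, adjusted p = 0.124), and none of these passed. By limma, 0 genes had a positive and 0 a negative slope past the threshold, with 1067 at an unadjusted p under 0.05. Cep78 passed without 0.5% quercetin replicate 3, at -1.08, and Sh3pxd2b without STZ replicate 6, at -1.12. These were the only 2 of 18 fits without 1 mouse that called a gene. Of the lists, 13 passed camera, among them male-biased genes with a mean slope of 0.84, female-biased genes of -0.80, p53 targets of -0.59 and NRF2 targets of -0.50, and 0 passed with an estimated correlation (smallest adjusted p = 0.26). Without 0.5% quercetin replicates 5 and 6, 4 lists passed. Of the 13, male-biased genes passed in the same direction, with a mean slope of 0.46, and interferon response genes passed in the opposite direction, with 0.18 (adjusted p = 0.0427) against -0.25 in the fit with all mice.

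**Figure D3:**
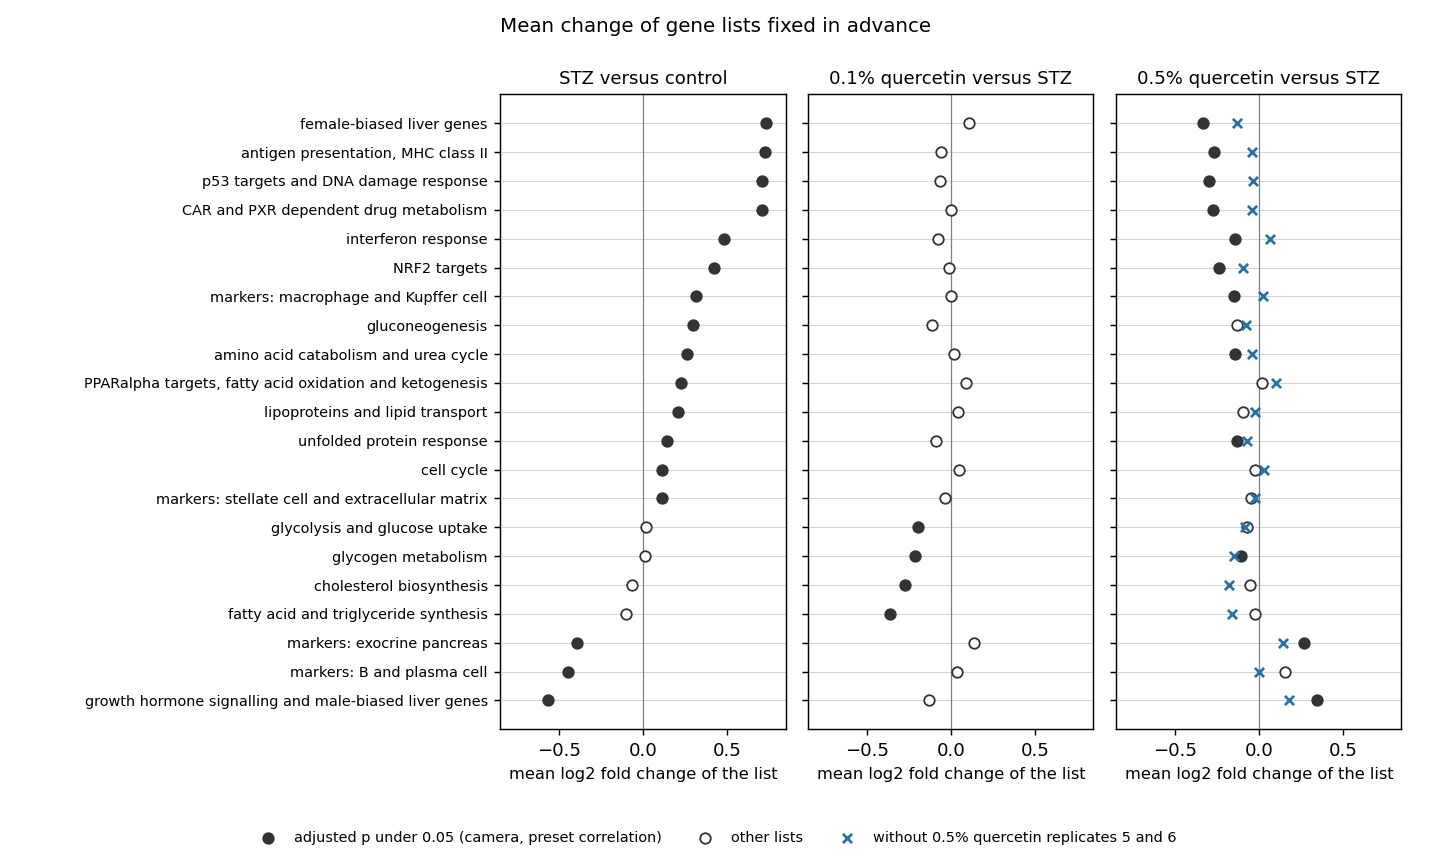
Mean log2 fold change of gene lists in STZ against control and in each quercetin group against STZ, with filled points for lists past camera and crosses for the fit without 0.5% quercetin replicates 5 and 6. The p53 targets lay at 0.71 in STZ against control and at -0.30 in 0.5% quercetin against STZ, and fatty acid synthesis lay at -0.36 in 0.1% quercetin against STZ.

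How far quercetin moved the STZ changes back toward control was measured on 137 genes called on control and STZ replicates 1 to 3. At 0.1% quercetin the share of the STZ change reversed was -0.328% (exact permutation p = 0.976, two-sided, n = 6 against 3). At 0.5% it was 37.3% (exact permutation p = 0.214, n = 6 against 3), and 5.77% without replicates 5 and 6 (exact permutation p = 0.6, n = 4 against 3). Over all 20 splits of the STZ and control arrays, the medians were -2.48% (-30.6% to 5.52%) at 0.1% and 38.6% (31.7% to 44.0%) at 0.5% quercetin. No split gave a p under 0.05. The changes of both doses against the same STZ arrays had a correlation of 0.368 across genes, which are not independent replicates. Simulated unchanged groups that share arrays gave 0.501 (0.225 to 0.723). Split STZ arrays gave -0.09 and 0.032.

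Against the control mice, the lists of p53 targets, NRF2 targets and female-biased genes shifted upward at 0.1% quercetin, with 12 of 24, 10 of 27 and 7 of 14 members higher. The lists of male-biased genes and fatty acid synthesis shifted downward, with 9 of 18 and 7 of 21 lower. Of the 17 lists past camera in this comparison, 0 passed with an estimated correlation (smallest adjusted p = 0.0663, for MHC class II). With fry, 19 of 38 lists passed, and 20 passed the exact permutation test of the list mean per mouse. Cplane1 rose by 4.27 (SE 0.62), Cyp4a14 by 3.18 (SE 0.62), Nnmt by 3.07 (SE 0.53), Cyp2c39 by 2.90 (SE 0.47) and Cyp2b9 by 2.64 (SE 0.48), each above all controls in 6 of 6 mice. Hsd3b5 fell by 2.77 (SE 0.52), Serpina4-ps1 fell by 2.64 (SE 0.50), and Serpina12 fell by 2.55 (SE 0.52). The fatty acid-binding protein gene Fabp5 fell by 2.20 (SE 0.51), and the elongase gene Elovl3 fell by 2.05 (SE 0.53). Fasn fell by 1.15 (SE 0.28, adjusted p = 0.0118), Srebf1, a regulator of lipogenesis, fell by 0.67 (SE 0.19, adjusted p = 0.034) and Scd1 fell by 0.64 (SE 0.18, adjusted p = 0.034), while Mt1 rose by 2.02 (SE 0.46, adjusted p = 0.00869). Whether these effects differ from those of STZ mice was tested in the comparison with STZ, where none of these genes passed.

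Of 21 fatty acid synthesis genes, 7 fell and 0 rose (14 and 0 adjusted over the list alone), with a mean of -0.46 (camera adjusted p = 7.92e-07, and adjusted p = 0.122 with an estimated correlation). Of 20 cholesterol synthesis genes, 4 fell and 0 rose (6 and 0 adjusted over the list alone), with a mean of -0.34 and an adjusted p = 0.412 with an estimated correlation. Of 24 p53 targets, 12 rose and 2 fell (15 and 2 adjusted over the list alone), among them Phlda3 by 2.33, Cdkn1a by 2.51 and the polo-like kinase gene Plk2 by 1.47. Of 27 NRF2 targets, 10 rose and 0 fell (14 and 1 adjusted over the list alone), among them Gsta2 by 2.24, Ephx1 by 1.65 and the glutathione transferase gene Gstm3 by 1.04. Interferon genes rose in 7 of 23 cases (14 adjusted over the list alone), with Usp18 at 1.24, Irf7 at 0.99 and Gbp3 at 0.89. MHC class II genes rose in 6 of 7 cases (6 adjusted over the list alone), with H2-Eb1 at 1.06, H2-Aa at 1.05 and H2-Ab1 at 0.80, and macrophage markers in 5 of 14 (7 adjusted over the list alone), with Cd5l at 0.66, C1qb at 0.64 and Mpeg1 at 0.54. Of 14 female-biased genes, 7 rose (9 adjusted over the list alone), among them Cyp17a1 by 1.97 and the thioesterase gene Acot3 by 1.36. Of 18 male-biased genes, 9 fell and 0 rose (11 lower and 1 higher adjusted over the list alone), among them the transporter gene Slco1a1, which fell by 1.30. Of 19 CAR and PXR genes, 6 rose and 1 fell (9 and 1 adjusted over the list alone), with Cyp2c38 at 2.25. These lists had camera adjusted p of 5.69e-10 for p53 and interferon, 5.8e-09 for NRF2, 7.46e-09 for female-biased, 1.86e-08 for MHC class II, 2.36e-07 for male-biased and macrophage, and 7.72e-07 for CAR and PXR genes. None of them passed with an estimated correlation.

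In all, 385 genes were higher and 346 lower at 0.1% quercetin than in controls (limma), with 2483 at an unadjusted p under 0.05. The share that were higher, 52.7%, was 29.2% under median scaling (222 higher and 539 lower), and the counts on the values as deposited were 127 and 90. Without 0.1% quercetin replicate 5 they were 244 and 196, and without 0.1% quercetin replicate 6 they were 249 and 211. The Gapdh 3' minus 5' difference, -0.31 ± 0.13 at 0.1% quercetin, moved with these gene groups as well, and with it in the fit 2 genes were higher, Ifi27l2b and Aebp2, and 0 lower, with 1496 at an unadjusted p under 0.05. Of the genes higher in STZ and in 0.1% quercetin mice against the same controls, 192 were shared, where independent lists give 7.81 and simulated unchanged groups gave 0. Unchanged groups call almost no genes, so their overlap lies near 0 in advance. Only the fits with split controls bear on the sharing of controls. With the controls split between the comparisons, 91 were shared of 158 and 209, where independent lists give 2.52. Of the lower genes, 139 were shared (5.86 for independent lists, 0 simulated), and 36 of 127 and 98 with split controls (0.949 for independent lists).

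Against the control mice, 0.5% quercetin mice had 7 genes higher and 10 lower (limma, 1612 at an unadjusted p under 0.05). Cplane1 rose by 3.08 (SE 0.62), Phlda3 by 1.63 (SE 0.31), the mannose-binding lectin gene Mbl2 by 0.85 (SE 0.17), the sulfatase gene Sulf2 by 0.81 (SE 0.17), Ifi27l2b by 0.58 (SE 0.12), the p53 family gene Trp73 by 0.53 (SE 0.10) and Aebp2 by 0.34 (SE 0.07). Of these, Ifi27l2b and Aebp2 were above all controls in 6 of 6 mice, Cplane1, Sulf2 and Trp73 in 5, and Phlda3 and Mbl2 in 4. Of the lower genes, Tcf24 changed by -1.08 (SE 0.17, adjusted p = 0.00734), Rnase2a by -0.97 (SE 0.20), the ephrin gene Efna1 by -0.80 (SE 0.16), Tspan33 by -0.67 (SE 0.13) and Arf5 by -0.61 (SE 0.12). Vamp5 changed by -0.54 (SE 0.11), Pcbp4 by -0.54 (SE 0.11), Ccdc47 by -0.53 (SE 0.09), the mitochondrial ribosomal protein gene Mrpl12 by -0.51 (SE 0.09) and Nat9 by -0.41 (SE 0.08). Of these, Tcf24, Rnase2a and Tspan33 were below all controls in 5 mice and the others in 6 of 6. The other probe sets of Ccdc47 differed by -0.06, 0.07 and 0.17. Trp73 had a control mean of 4.31 on the log2 scale, near the floor, and its other probe set, under the filter, differed by -0.16. Cdkn1a differed by 1.67 (SE 0.50, adjusted p = 0.153), and without 0.5% quercetin replicates 5 and 6 it rose by 2.84 (SE 0.25, adjusted p = 4.61e-08). Those replicates lay with the controls, for Cdkn1a too. Leaving them out widens the difference by construction, so that p is no separate test. All 17 calls ended in a limma fit on these groups alone (0 higher and 0 lower, 1468 at an unadjusted p under 0.05), in which the log2 changes were the same. Most of the 17 calls ended without the filter (0 and 3, 1943 unadjusted). Most also ended with the Gapdh difference in the fit (0 and 2, 1236 unadjusted) and with the replicate block (3 and 3).

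Interferon response genes at 0.5% quercetin had a mean of 0.34 against controls, MHC class II genes of 0.46, p53 targets of 0.41, PPARalpha targets of 0.24 and CAR and PXR genes of 0.44, and B and plasma cell markers had a mean of -0.29. Of 38 lists, 11 passed camera and 0 passed with an estimated correlation (smallest adjusted p = 0.11). Adjusted over the list alone, 12 interferon genes and 6 MHC class II genes were higher, and 14 p53 targets were higher and 1 lower. Without 0.5% quercetin replicate 5 the counts were 75 genes higher and 62 lower, without replicate 6 they were 88 and 62, and without both 233 and 199, which included all 17 genes. Both replicates lay with the controls, so larger counts without them follow from that and are no separate evidence. Without 0.5% quercetin replicate 1, 4 genes were higher, and without replicates 2, 3 and 4 the counts of higher and lower genes were 1 and 3, 1 and 1, and 0 and 1. Without control replicates 1, 2, 3 and 4 they were 0 and 2, 0 and 4, 0 and 2, and 1 and 2. In the fits without 0.5% quercetin replicates 2, 3 and 4 and without control replicates 1 to 4, the genes called were Tcf24, Ccdc47, Mrpl12, Vamp5, Efna1, Trp73 and, chosen after its values were seen, Hopx. The share of higher genes, 41.2%, was 25% on the values as deposited, 5.39% under median scaling and 53.3% under trimmed mean scaling. Of the 7 genes that were higher, 6 were also called in STZ mice (0.142 for independent lists, 0.01 simulated), and of the 10 lower genes, 8 were (0.169 for independent lists, 0.01 simulated). With the controls split, 0 genes were called at 0.5% quercetin, so the overlap could not be tested on separate controls. The simulated overlaps do not test it either, since unchanged groups call almost no genes.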

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

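The tests of the label exchange, of a lost STZ response, of the quercetin dose, of RNA quality and of the beta-actin difference were chosen after the results they bear on were seen.

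At 0.5% quercetin, replicates 5 and 6 lay with the controls on the axis from control to STZ and had control-like levels of Cdkn1a, Phlda3 and Cplane1, with Gapdh 3' minus 5' differences of -0.05 and 0.003 against means of -0.04 in controls and -0.34 in STZ mice. An exchange of labels with control mice would need a control near the STZ mice, and the highest control lay at 0.154, although control replicate 1 lay at 0.485 on the values as deposited. Scaling of the arrays was argued against, since the higher of the 2 mice lay at most at 0.117 under 4 scalings. A mouse without a lasting STZ response or with a single wrong label (higher position of the 2 mice 0.0519) and an effect of 0.5% quercetin in some mice only (lowest position of the other 4 mice 0.788) cannot be told apart, since no glucose value or second sample of these mice was analysed here. Both stay candidate explanations.

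The Gapdh 3' minus 5' difference was lower in STZ than in control mice. RNA quality as the whole cause of the STZ changes was argued against by the slope of the 488 called genes on that difference within groups. The slope was fitted on the control, STZ and 0.1% quercetin groups and gave a share of 0.181 (jackknife SE 0.043, 18 arrays) of their change. The called genes kept a share of 0.986 with the beta-actin difference in the fit, which decides nothing, since that difference itself was only -0.11 between the groups (exact permutation p = 0.409). With the Gapdh difference in the fit of all arrays the genes kept a smaller share, 0.655, and the median SE rose from 0.118 to 0.145. Thus 5 calls were left, through both a smaller change and a larger error. Without the 0.5% quercetin arrays they kept a share of 0.819 and 94 calls were left. That share restates the slope on the same 18 arrays and is no separate test. A part of the STZ changes may go with RNA quality, and an effect of STZ on the Gapdh transcript itself was not tested.

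Of 324 groups of 6 values of named genes and array measures, 12 had a mouse far from the others, where chance gives 16.2. This gap is that of the single most extreme mouse. It can miss 2 mice that lie together, such as 0.5% quercetin replicates 5 and 6. The gap as a share of the range was 0.688 for C1qb in control replicate 2, 0.72 for Cyp17a1 in control replicate 1, 0.636 for H2-Ab1 and 0.69 for Nrp1 in control replicate 5. In STZ mice it was 0.662 for Cyp1a1 and 0.662 for Ephx1 in replicate 2, 0.638 for Cyp4a14 and 0.648 for Gstm3 in replicate 6, and 0.645 for H2-Ab1 in replicate 1. At 0.1% quercetin it was 0.659 for Arf5 in replicate 4 and 0.759 for Trp73 in replicate 1, and at 0.5% quercetin 0.646 for Pcbp4 in replicate 2.

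The effects of the doses differed for 11 lists by camera, with mean differences of 0.33 for fatty acid synthesis, 0.22 for cholesterol synthesis, -0.14 for lipoproteins, -0.27 for CAR and PXR genes, -0.23 for NRF2 targets, -0.23 for p53 targets, -0.27 for acute phase genes, 0.48 for male-biased genes, -0.44 for female-biased genes, -0.16 for amino acid breakdown and -0.15 for macrophage markers. With an estimated correlation 0 of these passed, and 23 of 100 splits gave as many lists. Without 0.5% quercetin replicates 5 and 6, 3 of the 11 passed in the same direction and 3 turned (p53 targets to 0.0308, macrophage markers to 0.0256, and CAR and PXR genes in camera direction at -0.0378). Of 3318 probe sets without a gene symbol, which no comparison of genes used, 33 passed in STZ against control, 25 higher and 8 lower.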

How the results depend on the processing

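The values as deposited, trimmed mean scaling, the fit without 0.5% quercetin replicates 5 and 6 and the Gapdh, beta-actin and clock score covariates were chosen after the data were seen. Those replicates lay with the controls. Without them, larger differences of the group from controls and smaller ones from STZ mice follow by construction. No list past the threshold in the main fit turned its direction under any scaling of the arrays. Nor did any named gene that was called in the main fit or under that scaling. The direction of other lists and of named genes called in neither fit was not compared. The median of all genes in the dose trend was -0.148 on the values as deposited and -0.138 under median scaling. No detection calls were used here, so signal over background limits genes near the floor. Residuals of arrays of the same replicate number had a mean correlation of 0.012 across genes, against -0.0022 for different numbers, so the numbers were not used as pairs, although 6 genes passed for the number term and a factor shared by arrays of a number was not excluded. Causes not named here were not tested.

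In STZ against control, the values as deposited gave 120 genes higher and 41 lower, of which 160 were among the 488. Median scaling gave 170 higher, an added constant of 1 gave 140 lower, array weights gave 424 and 363, the Gapdh covariate gave 4 and 1, and the beta-actin covariate gave 147 lower. Leaving out 1 mouse gave 146 to 257 higher and 100 to 209 lower.

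In 0.1% quercetin against control, the values as deposited gave 127 and 90, median scaling 222 and 539, and the Gapdh covariate 2 and 0. Leaving out 1 mouse gave 244 to 433 higher and 196 to 383 lower. In 0.1% quercetin against STZ it gave 0 to 0 in each direction, in 0.5% quercetin against STZ and in 0.5% against 0.1% quercetin 0 to 0 higher and 0 to 1 lower, and in the trend 0 to 0 higher and 0 to 1 lower. The trend had 1 gene lower with the mean of all probe sets (Cep78) and 2 with an added constant of 1 (Cep78 and Sh3pxd2b).

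In 0.5% quercetin against control, no filter gave 0 higher and 3 lower (Ccdc47, Tcf24 and Mrpl12), the mean of all probe sets 1 and 5, the values as deposited 2 and 6, median scaling 37 and 649, an added constant of 1 gave 3 and 3, array weights 58 and 48, the replicate block 3 and 3, and the Gapdh covariate 0 and 2 (Ccdc47 and Sp3). Trimmed mean scaling gave 16 higher, an added constant of 64 gave 1 higher, and trend and robust estimation gave 2 higher. A fit by limma on these groups alone gave 0 and 0, with 1468 at an unadjusted p under 0.05. Without replicates 5 and 6 the counts were 233 and 199. Leaving out 1 mouse gave 0 to 88 higher and 1 to 62 lower.

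With an estimated correlation, the number of lists past the threshold was 1 in STZ against control, 2 in 0.1% quercetin against STZ and 0 in each of the other 5 comparisons. With fry it was 14 in STZ against control, 19 in 0.1% quercetin against control and 3 in 0.5% quercetin against control. It was 2 in each quercetin group against STZ, 0 between the doses and 1 in the trend. The exact permutation test of the list mean per mouse passed 14 lists in STZ against control, 20 in 0.1% quercetin against control and 2 in 0.1% quercetin against STZ. It passed 0 lists in 0.5% quercetin against STZ, between the doses and in 0.5% quercetin against control. Without replicates 5 and 6 the number of lists past camera was 5 in 0.5% quercetin against STZ, 5 between the doses, 17 in 0.5% quercetin against control and 4 in the trend. In that fit the means turned to 0.0647 for interferon genes and 0.0276 for macrophage markers in 0.5% quercetin against STZ, to 0.0308 for p53 targets and 0.0256 for macrophage markers between the doses, and to 0.18 for interferon genes and 0.0572 for macrophage markers in the trend. Of these, the interferon genes in the trend passed in the opposite direction (adjusted p = 0.0427) and the others did not pass. The cause was not tested. The mean of CAR and PXR genes between the doses was -0.0378, with a camera direction that turned.

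The reversal at 0.1% quercetin was 3.48% without a split and 4.30% on the values as deposited, against -0.328% (exact permutation p of 0.719, 0.857 and 0.976), and the cause was not tested. With genes called on replicates 4 to 6 it was -11.9% (exact permutation p = 0.452). At 0.5% quercetin it was 41.3% without a split (exact permutation p = 0.0195), where genes are chosen on the STZ arrays they are compared with. Of 176 values of named genes, 155 kept their side of the threshold, and their direction where called, on the values as deposited. The counts were 170 under median scaling, 176 under trimmed mean scaling and 96 with the Gapdh covariate.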

Other observations

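The tests of the clock genes and of the clock score were chosen after the results they bear on were seen, while the splits were planned.

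Genes of bile acid synthesis and transport moved both ways in STZ against control, a group chosen after its values were seen. Of 19 tested, 3 rose and 4 fell. The transporter gene Slco1a4 rose by 1.56, the reductase gene Akr1d1 by 0.66 and the phospholipid exporter gene Abcb4 by 0.64. The transporter gene Slco1a1 changed by -0.96, the hydroxylase genes Cyp7b1 by -0.83 and Cyp27a1 by -0.26, and the racemase gene Amacr by -0.25. The mean was 0.06 and the median -0.15.

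Clock genes, singled out after their values were seen, followed the replicate number across the groups. Dbp, a clock output gene, deviated from its group mean by -1.29, -0.87, 0.23, 0.34, 0.85 and 0.73 on average in replicates 1 to 6, and Arntl, a clock activator, by 0.65, 0.51, -0.04, -0.09, -0.58 and -0.44. Differences between arrays of a number that act on all genes were argued against, since 0 of the other lists reached the mean F of 3.79 of the clock list (highest 2.27). The permutation p of 0.0021 over 10000 renumberings within groups restates that clock genes followed the number. Whether tissue of a number was collected at a like time of day stays open, since collection times were not analysed here.

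The clock score had a mean of -0.29 ± 1.69 in STZ mice and 1.88 ± 1.96 at 0.1% quercetin (SD, n = 6 each, exact permutation p = 0.0736, adjusted p = 0.436 over 24 tests). The permutation did not take the replicate number into account. With that score in the fit, the mean of the 4 lists that were lower at 0.1% quercetin kept 70.3% of its size. By camera at the preset correlation, glycolysis had -0.14 (adjusted p = 0.0153), glycogen metabolism -0.25 (adjusted p = 2.15e-05) and fatty acid synthesis -0.22 (adjusted p = 0.000336). Cholesterol synthesis had -0.12 and no longer passed (adjusted p = 0.0732). An estimated correlation was not used with the score. Without the score, fatty acid and cholesterol synthesis did not pass with an estimated correlation.

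Of 100 splits of the same arrays, the real one counted, 1 called as many genes as the 488 of STZ against control (highest other 1), and 1 as many as the 731 of 0.1% quercetin against control (highest other 12). Both counts lay far above every other split drawn, and both shares lay under the planned limit of 0.05. A share under 1 of 100 cannot be reached with 100 splits, and these shares are not adjusted over the comparisons. For 0.5% quercetin against control, 6 of 100 splits called as many as 17 genes and the highest other called 85, so chance was not excluded, and a split that calls several times the real count points to a structure of the samples. For 0.1% quercetin against STZ, 0.5% quercetin against STZ, 0.5% against 0.1% quercetin and the trend, limma called 0 genes in the real split, with 687, 985, 1094 and 1067 at an unadjusted p under 0.05. With a real count of 0 all 100 splits call as many by construction, which tests nothing, and the highest others were 33, 2, 7 and 2. For lists, 2 of 100 splits gave as many as the 17 of STZ against control (highest other 19) and 2 as many as the 17 of 0.1% quercetin against control (highest other 17). Both shares lay under the planned limit of 0.05, although in each case another split gave at least as many lists. These shares, and that of the trend, are not adjusted over the comparisons, so they do not by themselves exclude chance. For the 13 lists of the trend, 4 of 100 splits gave as many and the highest other gave 14, a share only just under that limit. Of these 13 lists, 0 passed with an estimated correlation and 1 with fry. Without 0.5% quercetin replicates 5 and 6, 1 passed in the same direction and 2 turned, of which interferon response genes passed in the opposite direction (mean slope 0.18, adjusted p = 0.0427). The planned limit was not met for the 4 lists of 0.1% quercetin against STZ (62 of 100, highest other 14) and the 13 of 0.5% quercetin against STZ (10 of 100, highest other 18). Nor was it met for the 11 between the doses (23 of 100, highest other 16) and the 11 of 0.5% quercetin against control (18 of 100, highest other 17). Chance was not excluded for these lists.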
